A study of Mus musculus with 8 samples.

How the data were processed

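Gene expression was measured on 8 arrays of the Illumina mouse BeadChip kind, hybridised with biotin-labelled RNA from naive CD4+ T cells of C57BL6/NCrl mice. Per the labels, cells negative for CD44, CD25 and DX5 and positive for CD62L and CD4 were sorted from lymph nodes and spleen. They were cultured with plate-bound antibody to CD3e and soluble antibody to CD28 on wells that also carried either Delta4-Ig, a fusion of the Notch ligand Delta-like 4 to an immunoglobulin tail, or control Ig. RNA was taken at day 1 or day 3. The labels number the mice. At day 3 each stimulus has mouse 1 and mouse 2, and mouse 1 has a second array that the titles call a technical replicate. At day 1 each stimulus has 1 sample, from mouse 1. The 8 arrays therefore stand for 6 samples from 2 mice. All of them lie on 1 chip, so chip and scan are not confounded with the stimulus.

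The authors deposited a non-normalized table that holds, per array and probe, an intensity on a linear scale that is neither background-subtracted nor normalized between arrays. The same deposited table gives a detection p-value per probe and array. GenomeStudio and limma are named, without versions or roles, per the submitters' processing notes. The authors also deposited a table of processed log2 values of the same arrays, on which no scale is stated. Set against the values computed here it differed by at most 0.0417 on any array and correlated with them at 1.00 on each, so it was read as background-corrected, quantile-normalized log2 intensity. Its column median was 5.28 on each array. It was used only as an alternative.

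The intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p-values, with an offset of 16. Probes were kept when their detection p-value lay under 0.01 on at least 2 of the 8 arrays. Of 25697 probes, 10744 were kept. The annotation table gave 1 gene symbol for 23978 probes and several for 0. It left 1719 unnamed here, and no probe was named in another way. A gene was represented by its probe with the highest mean over all arrays, which gave 7504 genes. Other detected probes of a named gene were checked for sign, and at day 3 the only disagreement among the genes named by the rule was Nusap1, whose difference lay near 0 and where 1 of 2 had the same sign.

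Signal over background limits these arrays. Between 8940 and 10543 probes, 34.8% to 41.0% of the total, were detected per array, and the raw 75th percentile ran from 322 to 480. Where a gene was detected on no array of a group, only a bound is given: the mean of the bright group over all its samples against the mean, per array, of the higher of the lowest detected signal and the probe's own value. Such folds are written as at least so many fold, and the log2 differences printed for these genes are fitted values, not bounds. Where only some arrays of a day 3 group detected a gene whose change is printed, their number is given, and the change is measured against a level partly at background. The number of arrays limits the precision of every value. The technical arrays of mouse 1 differed from each other with an SD of 0.284 log2 units with control Ig and 0.285 with Delta4-Ig. The 2 mice differed with an SD of 0.746 with control Ig and 1.06 with Delta4-Ig.

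Technical arrays were averaged before any test. One linear model with the 4 groups was fitted with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. This fit had no term for the mouse and 2 residual degrees of freedom, all from day 3. Day 1 samples were assumed to vary like those of day 3. The second fit held the mouse number as a block, since the labels give the same number to samples of 1 animal. Across probes, the difference between mouse 2 and mouse 1 correlated at r = 0.607 between the 2 stimuli at day 3, so samples of 1 mouse deviated together. That fit kept 1 residual degree of freedom and drew most of its error estimate from the other probes, with 6.08 prior degrees of freedom. The fit without the block was fixed as the main one before the data were examined, and the block was listed then as an alternative. Both are given for each result, since the first called no probe in any contrast. The variants of the blocked fit were added after its calls had been seen. The words rose and fell are used only for probes past the threshold in the fit with the mouse as a block, and for gene lists past the threshold of their own test.

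The day 3 contrast was Delta4-Ig minus control Ig, and the time contrast was the mean of the day 3 groups minus the mean of the day 1 groups. Day 1 was described without a test, by the difference between 2 samples. Before the data were examined, 36 gene lists with 568 genes were fixed, of which 366 genes were measured here. The 31 lists with at least 3 measured members were tested with camera at its preset correlation between genes of 0.01, with adjustment over the lists. The same test with an estimated correlation, and fry, were alternatives. With an estimated correlation camera uses only the residual degrees of freedom of the fit, 2 without the block and 1 with it. A list could therefore hardly pass it here. Its failure does not show that correlation between genes made the call at the preset value. Day 1 lists were placed by their median among 10000 random lists of the same size and matched mean expression.

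The rule for named genes was also fixed then. At day 3 it took the 12 higher and 12 lower genes with the largest change past the threshold that moved the same way in both mice, or, with fewer than 5 probes past it, the 10 with the smallest p. It also took the members of each list past the threshold, the 2 members of each list with the largest change, all measured Notch targets and 9 further genes. Day 1 and the time contrast each gave 8 higher and 8 lower genes, and the difference between the day 3 and day 1 effects gave the 5 smallest p. RIKEN, predicted and accession-like names were skipped. Applying the rule to the fit with the mouse as a block was decided after the fit without it had called no probe.

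The scripts were tested on simulated data with changes of known size. For the day 3 contrast over 10744 probes, the fit with the mouse as a block recovered 0% of changes of 1 log2 unit, 37.9% of changes of 2 units and 95.5% of changes of 4 units, with 2 of 90 calls on unchanged probes. In 20 simulations with no change it called at most 16 probes. The fit without the block recovered 0% at each size. The simulated data held the same mouse difference with both stimuli and noise independent between probes, which is what the blocked fit assumes. In the real data the mouse differences correlated at r = 0.607 between the stimuli. These figures therefore do not show how many of the real calls are false. Alternatives covered background correction, normalization, the offset, the detection filter, the handling of technical arrays, the mouse block, the spread estimate, the samples in the fit and the leaving out of each day 3 sample. Figures were drawn with matplotlib 3.10.9.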

Results

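The series asked what the Notch ligand Delta-like 4 does to gene expression in CD4+ T cells that are activated for the first time. Naive mouse CD4+ T cells were stimulated through CD3 and CD28 with plate-bound Delta4-Ig or control Ig, and RNA was measured at day 1 and day 3. Day 3 held 2 mice per stimulus and day 1 held 1 mouse per stimulus, so only day 3 has replicates. Per array, 8940 to 10543 of 25697 probes were detected. Values are normalized log2 intensities, errors of differences are SE of the fit with the mouse as a block, and day 3 levels are mean ± SD over 2 mice.

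At day 3, cells cultured with Delta4-Ig carried far more mRNA for the cytokine Il10 than cells with control Ig. Il10 stood at 11.84 ± 1.09 with Delta4-Ig, was detected on 0 of the 3 control arrays, and was at least 51.1-fold higher (log2 difference 6.79 ± 0.36, 7.28 in mouse 1 and 6.30 in mouse 2). Il21, a cytokine of helper T cells, and Havcr2, which encodes the inhibitory receptor TIM-3, each detected on 1 of 3 control arrays, rose by 4.44 ± 0.69 and 4.54 ± 0.53. In mouse 1 and mouse 2 the differences were 6.10 and 2.78 for Il21, and 5.69 and 3.39 for Havcr2. Il21 passed only narrowly (limma adjusted p = 0.0497 with the mouse as a block). The pseudokinase gene Trib2 rose 27.8-fold and Gcnt1, a glycosyltransferase of O-glycan synthesis detected on 2 of 3 control arrays, rose 17.8-fold. In the other direction Dapl1, a gene of naive T cells detected on 1 of 3 Delta4-Ig arrays, fell 19.9-fold, the chemokine receptor gene Ccr6 fell 11.4-fold, and Eomes, a transcription factor of cytotoxic and memory cells, was at least 4.58-fold lower. Without background correction the fitted log2 differences were smaller, at 4.56 for Il10, 2.87 for Il21, 2.88 for Havcr2, 4.02 for Trib2, 2.75 for Gcnt1, -2.64 for Dapl1, -2.73 for Ccr6 and -1.27 for Eomes. With an offset of 50 they lay between these and the values of the offset used, at 5.78 for Il10 and -3.65 for Dapl1.

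These statements rest on the fit that holds the mouse as a block, which placed 76 of 10744 probes past the threshold, 45 higher and 31 lower, for 35 and 25 named genes by any of their probes. The fit without the block, fixed beforehand as the main one, called 0 probes with limma. In it 302 probes had an unadjusted p under 0.05 where chance gives 537, and the smallest adjusted p was 0.330. The blocked count was 0 without background correction, 0 without the detection filter, 21 with detection required on all 8 arrays and 264 with 75th percentile scaling, and it reached 589 when technical arrays were counted as samples.

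The 10 smallest p-values of the fit without the block belonged to Trib2, Dapl1, Il10, Gcnt1, Adam19, Eomes, Ffar2, Slc1a2, Unc13b and Havcr2. None passed in that fit, with adjusted p from 0.330 to 0.645, and all 10 passed with the block. Adam19, a metalloprotease gene, differed by 3.17 ± 0.32. Ffar2, a receptor for short-chain fatty acids, was detected only with Delta4-Ig and was at least 4.77-fold higher. The glutamate transporter gene Slc1a2 and Unc13b were detected only with control Ig, at least 7.06-fold and 2.79-fold lower with Delta4-Ig. Without background correction the fitted log2 differences were 2.48 for Adam19, 1.47 for Ffar2, -1.88 for Slc1a2 and -1.07 for Unc13b.

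The remaining genes of the 12 with the largest increase with the block were Emp1, Plac8, Lpar3, Timp1, Selenbp1, Lgals3 and Cysltr1. Emp1, which encodes a membrane protein, was detected on 0 control arrays and was at least 33.3-fold higher. Plac8 rose 26.3-fold. Timp1, an inhibitor of metalloproteases detected on 1 of 3 control arrays, rose 18.6-fold, and Lgals3, the gene of galectin-3, rose 10.9-fold. Among the 12 largest decreases, Idi2 was at least 26.5-fold lower and Igfbp7, an insulin-like growth factor binding protein gene, fell 15.3-fold. Lad1, Oasl2, Slc17a6, Calhm6, Adh4, Otx1 and Tnfrsf13c fell by 2.94 to 3.86 on the log2 scale. Of these, Oasl2, Adh4 and Tnfrsf13c were detected on 1 of 3 Delta4-Ig arrays and Lad1, Slc17a6, Calhm6 and Otx1 on 2 of 3. Without background correction these 7 differed by -1.48 to -2.65, Emp1 by 3.80, Plac8 by 3.89, Timp1 by 2.83 and Idi2 by -3.40. Some sizes differed between mouse 1 and mouse 2, among them Emp1 (fitted 4.42 and 6.95), Timp1 (3.09 and 5.35), Idi2 (fitted -6.45 and -4.19) and Lad1 (-2.49 and -5.23). Tnfrsf13c encodes the receptor for the survival factor BAFF.

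**Figure D1:**
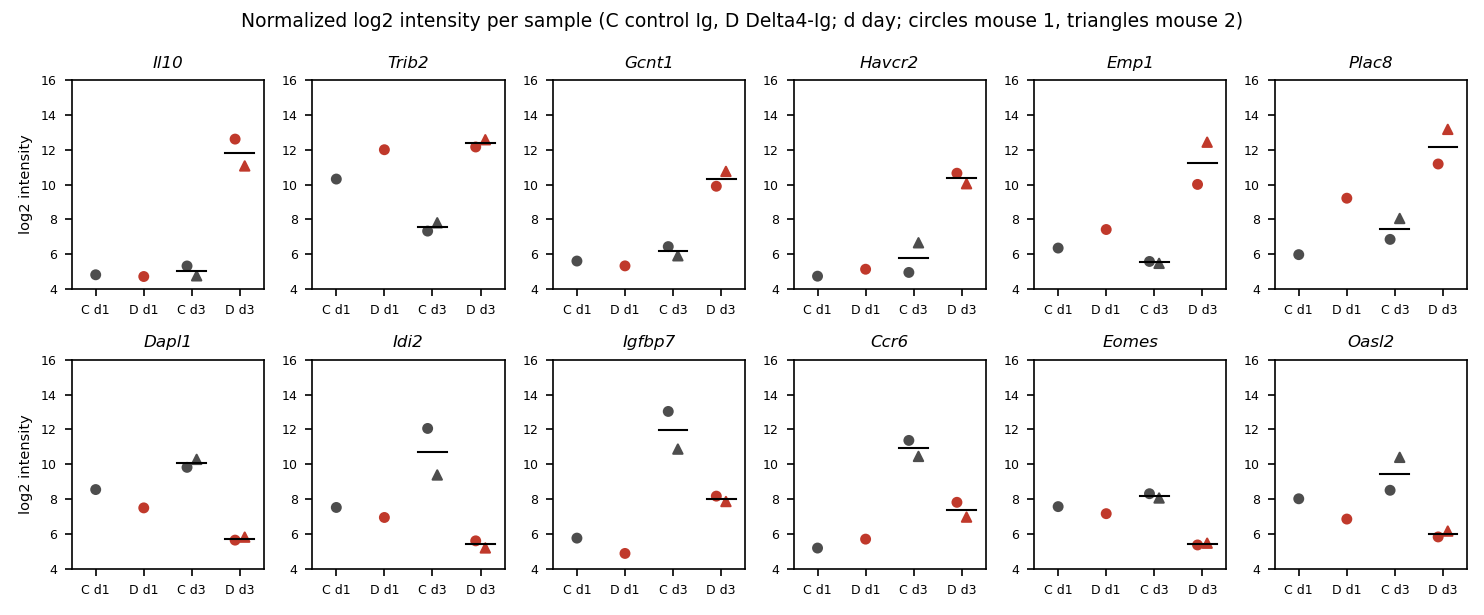
Normalized log2 intensity of 12 genes in each of the 6 samples, with control Ig in grey, Delta4-Ig in red, mouse 1 as circles, mouse 2 as triangles and day 3 means as bars. Il10 lies at 5.05 with control Ig and 11.84 with Delta4-Ig at day 3, and Dapl1 lies at 10.05 and 5.74.

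Targets of Notch signalling were higher as a group. Of 9 measured members, 1 rose, 0 fell and 8 did not pass, and adjusted over the list alone 5 were higher and 0 lower with the block. That milder adjustment did not single out this list. It gave 10 higher and 0 lower of 12 HIF targets, and 0 higher and 8 lower of 19 interferon-stimulated genes. Hey1, Hes1, Dtx1 and Nrarp were detected on 0 of 3 control arrays and on 3 of 3 Delta4-Ig arrays at day 3. Hey1 rose (fitted 2.64 ± 0.32, adjusted p = 0.0195) and was at least 3.36-fold higher. Dtx1 at a fitted 1.73, Hes6 at 1.47, Nrarp at a fitted 1.39 and Hes1 at a fitted 1.24 were higher in both mice without passing. Without background correction Hey1 differed by 1.16, Dtx1 by 0.65, Nrarp by 0.53 and Hes1 by 0.44. Notch1 (-0.32), Myc (-0.61), Il2ra (0.13) and Gata3 (-0.72) did not pass. The list's median was 1.24, or 0.24 with undetected genes at their bound (camera adjusted p = 0.00116). With an estimated correlation the adjusted p = 0.777. The 14 measured genes of the Notch receptors and their machinery had a median of 0.01 and 0 past the threshold.

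Genes of the hypoxia response and of glucose use were also higher as groups. Of 12 HIF targets, 11 were higher in both mice, 1 rose and 11 did not pass singly, and the list's median was 1.07 (camera adjusted p = 4.8e-07). With an estimated correlation the adjusted p = 0.777. Ndrg1 rose by 3.17 ± 0.40, and Egln3, an oxygen-sensing prolyl hydroxylase gene, at 2.41 did not pass. Of 18 glycolysis genes, Aldoc rose by 3.18 ± 0.34 and 17 did not pass, with a median of 0.62 (camera adjusted p = 0.000292, and adjusted p = 0.777 with an estimated correlation).

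Interferon-stimulated genes were lower. Of 19 measured, 16 were lower in both mice, 0 rose, 2 fell and 17 did not pass, with a median of -0.63 (camera adjusted p = 0.000103, and adjusted p = 0.777 with an estimated correlation). Oasl2 fell by 3.45 ± 0.42 and Usp18, which removes the ubiquitin-like protein ISG15, fell by 2.30 ± 0.31. The 17 nucleolar and ribosome biogenesis genes had a median of -0.78 with 0 past the threshold singly (camera adjusted p = 0.00108, and adjusted p = 0.855 with an estimated correlation). Their median was -0.13 in mouse 1 and -1.44 in mouse 2.

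Genes tied to cell survival were mixed. The 11 cytokine and TNF family receptors linked to T cell survival had a median of 0.68 with 0 past the threshold singly (camera adjusted p = 0.00591, and adjusted p = 0.777 with an estimated correlation). Il7r, the receptor for the survival cytokine IL-7, was 1.63 higher in mouse 1 and 1.47 higher in mouse 2 without passing (adjusted p = 0.102). Neither the 19 inhibitors of apoptosis nor the 22 apoptosis effectors shifted as a list, each with camera adjusted p = 0.923 and 0 genes past the threshold. Adjusted over each list alone with the block, 2 inhibitors were higher and 3 lower, and 1 effector was higher and 0 lower. Bcl2 differed by 1.00 ± 0.34, Mcl1 by 0.18 ± 0.38 and Bcl2l1, detected on 2 of 3 Delta4-Ig arrays, by -1.48 ± 0.31, and none passed over all probes. The 12 genes of IL-2 and STAT5 signalling passed only with the block (adjusted p = 0.0115, against 0.0611 without it, and adjusted p = 0.833 with the block and an estimated correlation), and among them Socs3, a feedback inhibitor of cytokine signalling, rose by 2.83 ± 0.39.

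Among helper T cell programmes, the 11 Th2 genes passed with a test direction of higher (camera adjusted p = 0.0236, and adjusted p = 0.777 with an estimated correlation), although their median was -0.01 and their mean 1.16. Il10 was the member that rose, and 10 did not pass. Il4 was 4.45 higher on the log2 scale in mouse 1 and at least 31.6-fold lower in mouse 2, where the Delta4-Ig array did not detect it, and Gata3 differed by 1.97 and -3.40. The 11 regulatory T cell genes had a median of 0.86, or 0.38 with undetected genes at their bound, and 0 past the threshold singly (camera adjusted p = 0.00591, and adjusted p = 0.777 with an estimated correlation). Nrp1 at -1.84 and Izumo1r at 1.79 did not pass. The 10 Th1 genes did not shift (adjusted p = 0.923), with Ifng at 1.00 ± 0.68 and Tbx21 at -0.93 ± 0.31. Il21 rose and Ccr6 fell among 5 Th17 genes.

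**Figure D2:**
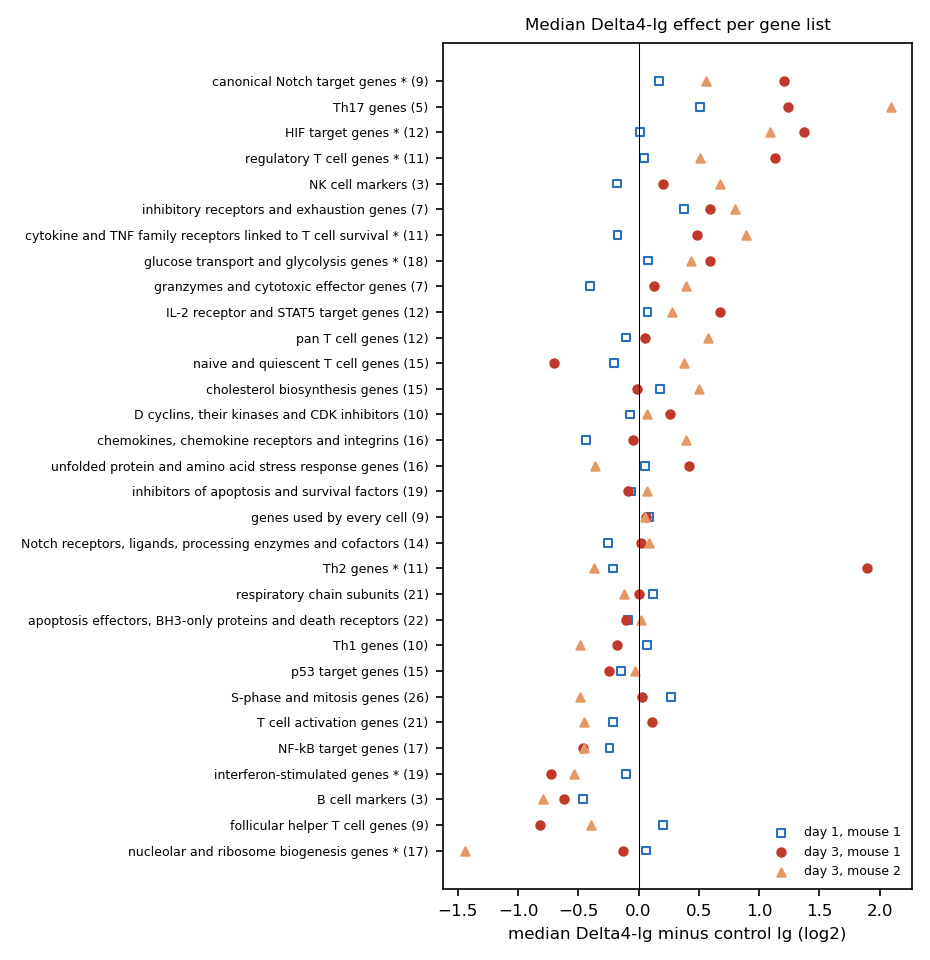
Median log2 difference of Delta4-Ig minus control Ig for 31 gene lists, with the number of measured genes in brackets, for day 1 (squares), day 3 mouse 1 (circles) and day 3 mouse 2 (triangles). A star marks the 8 lists with camera adjusted p under 0.05 at its preset correlation in the fit without the block, and 0 lists pass with an estimated correlation.

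Other lists gave single genes. Cd44, an adhesion receptor of activated cells, fell by 2.46 on the log2 scale among 21 activation genes. Among 16 chemokine and homing genes 1 rose and 1 fell, and Cxcr4, detected on 1 of 3 control arrays, was the gene that rose, by 3.05. Bcl3 rose by 2.43 among 17 NF-kB targets, whose median was -0.39, with 4 higher and 8 lower in both mice (camera adjusted p = 0.129). The 26 genes of S phase and mitosis had a median of -0.20 and 0 past the threshold (adjusted p = 0.0618). Of 3 measured B cell markers, H2-Ab1 rose by 2.72 ± 0.33, while Cd74 at -1.68 and H2-Aa at -0.70 were lower in both mice without passing. H2-Aa was detected on 2 of 3 arrays of each stimulus and was named after its values were seen.

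Differences between mice were of the size of those between stimuli. The SD of the difference between mice was 1.06 with Delta4-Ig and 0.746 with control Ig, against 0.604 for the stimuli in mouse 1 and 0.853 in mouse 2. At least 2-fold differences were counted for 542 genes in mouse 1 and 1379 in mouse 2. Both mice shared 160 higher and 88 lower genes, and 39 genes went in opposite directions. Across 7504 genes, which are not independent replicates, the effects of the 2 mice correlated at r = 0.371.

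**Figure D3:**
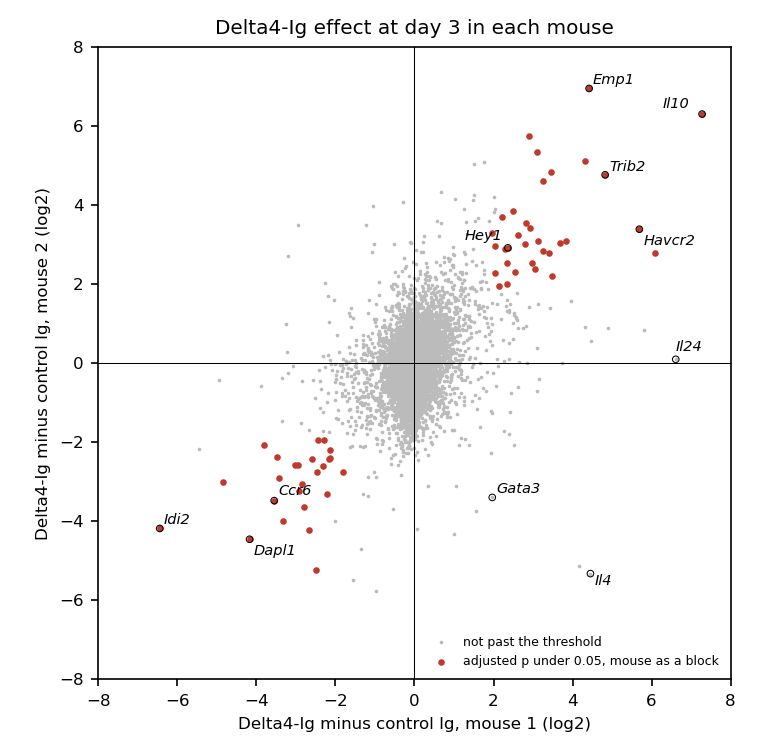
Log2 difference of Delta4-Ig minus control Ig at day 3 in mouse 1 (horizontal) and mouse 2 (vertical), 1 point per gene, with genes past the threshold of the blocked fit in red. Il10 lies at 7.28 and 6.30, and Il4 at 4.45 and a fitted -5.33 whose Delta4-Ig value was not above background.

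At day 1 the stimuli had separated little. The SD of the difference was 0.354, against 0.284 and 0.285 between technical arrays, and 105 of 6837 genes differed at least 2-fold, 64 higher and 41 lower. With 1 sample per stimulus no test was run within day 1, and there is no replicate check. Gjb2, a gap junction gene, was detected only with Delta4-Ig and was at least 5.82-fold higher. Plac8 (at least 7.93-fold), Isg15 (at least 7.41-fold), Lpar3, Il3, Fhdc1, Lif and Il1r2 were likewise detected only with Delta4-Ig. Rgs16, a regulator of G protein signalling, was 4.40-fold lower and Bcl6, which encodes a transcriptional repressor, 3.64-fold lower. Wars2 was 2.84-fold and Npas4 2.58-fold lower. Dctn1 (at least 3.17-fold), Grn (at least 2.16-fold), Mettl27 and Upk1a were detected only with control Ig. The count was 21 without background correction, 40 with an offset of 50 and 26 with detection on all 8 arrays. Of 31 lists, 6 had medians above and 9 below the central 95% of random lists. Genes of the random lists were drawn independently, while members of a list can vary together. Many lists can therefore lie outside without an effect of Delta4-Ig. By that placing the S phase and mitosis genes lay highest, with a median of 0.27, and chemokine and homing genes lowest, with -0.44.

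Across 7504 genes the day 1 and day 3 effects correlated at r = 0.053 with the mean of both mice, 0.172 with mouse 1 and -0.048 with mouse 2, which shares no animal with day 1. Over the 58 genes whose representative probe passed the blocked threshold at day 3, r = 0.399, and 32 had the same sign at day 1, against 3599 of all 7504 genes. Many of the 58, such as Ccr6, Havcr2, Gcnt1 and Igfbp7, were detected in neither day 1 sample. Their sign at day 1 is that of background, so the 32 is not a count of measured day 1 changes. Trib2 was 1.68 higher at day 1 and Plac8 3.24 higher, while Il10 was detected in neither day 1 sample.

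From day 1 to day 3, 866 probes passed with the block, 509 higher and 357 lower. Nusap1, a mitotic spindle gene, rose by 5.36 ± 0.31, Scd1, a fatty acid desaturase gene, by 4.81 ± 0.45, and the effector cytokine gene Ifng by 4.69 ± 0.68. Tgm2, Mgarp, Egln3, Tubb6 and Gja1 rose by 4.98 to 6.27. Scd1, Tgm2 and Mgarp were detected in neither day 1 sample, and Ifng, Egln3, Gja1 and Tubb6 in 1. Npas4 was detected on 0 of 3 Delta4-Ig arrays at day 3, so its value is fitted. Klf2, a transcription factor of quiescent T cells, fell by 3.49 and Npas4, an activity-induced gene, by 3.13, with Ipcef1, Chst2, Atp1b1, Rgl1, Pou2af1 and Ifi214 also lower. Without the block limma called 0, with 1492 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0512. The blocked count was 0 without the detection filter, 1458 with 75th percentile scaling and 271 without background correction, of which 192 were higher. Both day 1 samples come from mouse 1, so the blocked estimate of time rests on that animal. The genes named were ranked by the change over both mice, while the calls and errors come from the blocked fit. The change over both mice can differ from the blocked estimate. These were 4.66 and 5.28 for Igfbp7, which also passed, and 4.64 and 3.22 for Aldoc.

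As lists, 16 of 31 passed for time without the block, 15 higher and 1 lower, and 18 passed with it. With an estimated correlation 0 passed, and for the 16 the adjusted p ran from 0.490 to 0.625. S phase and mitosis genes rose (12 rose, 1 fell, camera adjusted p = 0.000567, and adjusted p = 0.586 with an estimated correlation), with a median change over both mice of 1.43 with control Ig and 0.31 with Delta4-Ig. Glycolysis genes (median 1.04) and HIF targets (median 1.76) rose, and ribosome biogenesis genes fell with a median of -1.06. These medians set day 3 of both mice against day 1 of mouse 1, so a difference between the mice enters them. For S phase and mitosis genes, Delta4-Ig minus control Ig at day 3 had a median of 0.03 in mouse 1 and -0.49 in mouse 2. Their median change over time was 0.88 without the block and 1.38 with it (camera adjusted p = 0.00022 with the block). With the mouse as a block the medians of glycolysis genes, HIF targets and ribosome biogenesis genes were 0.79, 1.55 and -0.49 (camera adjusted p = 7.26e-05, 0.000544 and 0.0164). Without the block and with an estimated correlation the adjusted p = 0.490 for glycolysis genes and HIF targets, and 0.625 for ribosome biogenesis genes. Lists of Th1, Th2, Th17, cholesterol synthesis, p53 target and interferon-stimulated genes were among the others that passed as higher.

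**Figure D4:**
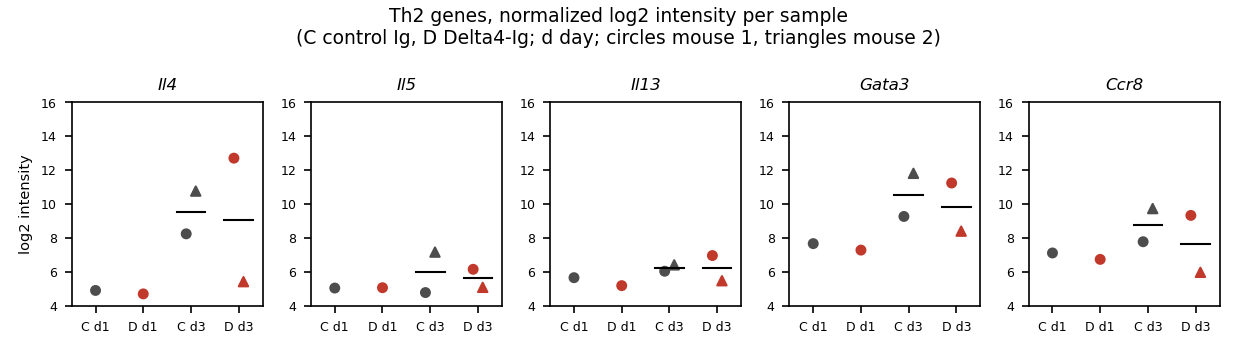
Normalized log2 intensity of 5 Th2 genes in each of the 6 samples, with control Ig in grey, Delta4-Ig in red, mouse 1 as circles, mouse 2 as triangles and day 3 means as bars. At day 3 Il4 is 4.45 higher with Delta4-Ig in mouse 1 and at least 31.6-fold lower in mouse 2, where the Delta4-Ig array did not detect it.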

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

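The tests of exchanged arrays, of a difference between the animals, of weak signal and of other cell types were chosen after the results were seen. So were the second correlation in the test of the time course, the rule that reads both, and the count of pairs without the authors' values.

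For the difference of the Delta4-Ig effects between day 3 and day 1, 8 gene lists passed camera at its preset correlation, with day 1, which has no replicates, assumed to vary like day 3. With an estimated correlation none passed, with an adjusted p of 0.96 for ribosome biogenesis genes and 0.792 for the other 7 lists. The median difference, day 3 minus day 1, was 1.08 for HIF targets, 0.839 for receptors linked to survival, 0.554 for glycolysis genes, 0.44 for pan T cell genes and 0.418 for Th2 genes. It was -0.846 for ribosome biogenesis genes, -0.635 for interferon-stimulated genes and -0.406 for S phase and mitosis genes. Day 1 holds mouse 1 only. The day 3 medians of mouse 1 and mouse 2 were -0.13 and -1.44 for ribosome biogenesis genes, 0.03 and -0.49 for S phase and mitosis genes, 0.05 and 0.57 for pan T cell genes and 1.89 and -0.37 for Th2 genes. No single probe passed for the difference of effects with limma, with 64 at an unadjusted p under 0.05 without the block and 370 with it. The 5 smallest p without the block belonged to Il10, Gcnt1, Ffar2, Dapl1 and Trib2.

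The Th2 genes Il4, Il5, Il13, Gata3 and Ccr8 had higher fitted values with Delta4-Ig in mouse 1 and lower ones in mouse 2 at day 3, a set picked after their values were seen. Gata3 and Ccr8 were detected on all day 3 arrays, while Il4, Il5 and Il13 were not detected with Delta4-Ig in mouse 2, and Il5 in mouse 1 allows no bound. Exchanged mouse 2 arrays are argued against, since 84% of the 144 genes outside the list that changed at least 4-fold in mouse 1 had the same sign in mouse 2. Normalization is argued against as well, since the opposite signs held in 20 of 20 pairs of gene and alternative normalization, or 15 of 15 without the authors' values, which nearly equal those used here. With control Ig, Il4 was already 2.51, Gata3 2.54 and Ccr8 1.95 higher in mouse 2 than in mouse 1 (the fitted median of all 5, 2.38, is that of Il5, which like Il13 was not detected on the control arrays of mouse 1), so a difference between the animals or their cultures stays open and, with 1 sample per mouse and stimulus, cannot be told apart from a Delta4-Ig effect that depends on the animal.

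The Delta4-Ig sample of mouse 2 at day 3 stood apart, with lower ribosome biogenesis genes. Weak signal is argued against by the number of detected probes, which was 10543 on that array against at most 9950 on the others. Raw intensity gave no such support. The raw mean of that array, 683, was the lowest at day 3, where the next was 702, and its raw 75th percentile was 387. Normalization is argued against, since the median of these genes in mouse 2 was -1.52 with 75th percentile scaling. A culture further along the course from day 1 to day 3 was tested by correlating mouse 2 minus mouse 1 with the time change of mouse 1, which gave r = -0.228, and the rule written beforehand would have excluded the explanation. That rule was wrong by design, because the day 3 deviation of mouse 1 enters both terms with opposite signs, and with the change to mouse 2, where the shared term has the same sign, r = 0.236. The explanation therefore stays open, as does a difference between the animals.

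H2-Ab1 rose with Delta4-Ig at day 3. More antigen presenting cells or B cells in the Delta4-Ig cultures are argued against, since Cd74 and H2-Aa, abundant in those cells, had a median change of -1.19. H2-Aa was detected on only 5 of the 8 arrays, so this rests mainly on Cd74. The values do not tell whether such cells were present with both stimuli, as Cd74 was detected on all 8 arrays. A fault of 1 probe is argued against, since the 3 other detected probes of H2-Ab1 were higher in both mice.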

How the results depend on the processing

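Variants of the blocked fit, of the day 1 lists and of the difference of effects were added after the data had been seen, and the other alternatives were planned. Without the block, the day 3 count of 0 probes became 49 with 8 arrays as samples, 3 with arrays of a sample as a random block and 76 with the mouse as a replicate block, and ran from 0 to 15 when 1 day 3 sample was left out. It was 15 without mouse 2 of control Ig and 1 without mouse 1 of control Ig. It stayed 0 in the other planned settings. The time count of 0 became 27 with an offset of 50, 44 with detection on all 8 arrays, 703 with 8 arrays as samples, 223 with a random block and 866 with the replicate block, and ran from 63 to 210 with 1 sample left out. The cause was not tested.

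With the mouse as a block, the day 3 count of 76 ran from 0 to 589 over 11 variants. It was 0 without background correction, 0 without the filter, 21 with detection on all 8 arrays, 264 with 75th percentile scaling, 589 with 8 arrays as samples and 250 with a random block, and lay within 1.5 times of 76 in 5 variants. All 76 calls were among the 264, and 35 were among the 49 calls of the unblocked fit on 8 arrays. The blocked time count of 866 became 271, 1458 and 0 without background correction, with 75th percentile scaling and without the filter. Leaving out a sample removes the residual degrees of freedom of the blocked fit, so it has no such test. Exchanging the stimuli within 1 mouse gave 0 probes against 76, but 1 of 2 groupings is too few for a share under 0.05.

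The 8 lists at day 3 became 0 with an estimated correlation, 0 with directional fry and 2 with mixed fry, and ran from 5 to 9 with 1 sample left out, with 5 without mouse 1 of Delta4-Ig. The block added IL-2 and STAT5 genes and changed no other list call. The 105 genes at day 1 became 21 without background correction, 40 with an offset of 50 and 26 with detection on all 8 arrays. Of 628 values of 44 genes, 556 kept direction and side, 59 passed the threshold and 13 reversed, in 6 genes that did not pass. With 8 arrays as samples Gata3 was 0.18, Il4 1.19 and Mcl1 -0.019, and Il4 was 0.28 without background correction. With 1 sample left out Gata3 ran from -2.13 to 0.70, Il4 from -4.07 to 3.20, Il2ra from -0.49 to 0.76, Ifng from -0.27 to 2.26, Mcl1 from -0.31 to 0.68 and Myc from -1.40 to 0.18.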

Other observations

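With the mouse as a term, the 2 mice differed at day 3: 311 probes were higher and 112 lower in mouse 2. The genes and lists named here were picked after their values were seen. Tspoap1 was 5.25 higher, Espn 4.15 and Aldoc, a glycolytic aldolase gene, 2.85, while the chemokine gene Ccl3 differed by -2.90 and Tnfsf4, which encodes OX40 ligand, by -2.78. HIF targets had a median of 1.12 and glycolysis genes of 0.55 in mouse 2 against mouse 1, and ribosome biogenesis genes of -1.21. With control Ig and with Delta4-Ig these medians were 0.90 and 1.25 for HIF targets, 0.74 and 0.55 for glycolysis genes, and -0.50 and -1.90 for ribosome biogenesis genes. These lists, among others, passed camera at its preset correlation, and with an estimated correlation the adjusted p = 0.878 for each. The first 3 principal components took 52.8%, 28.5% and 10.3% of the variance.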
